A study of Mus musculus with 4 samples.

How the data were processed

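Gene expression in proliferative-zone chondrocytes, the dividing cells of the growth plate, was measured on Affymetrix mouse arrays in 2 samples from control mice and 2 samples from mice in which Ift88 was deleted in Col2a-expressing cells. Per the labels, the zone was cut by needle from 40 µm sections of the tibia and femur at postnatal day 7, and 50 ng of total RNA per sample went through an amplification of 2 rounds with T7-linked oligo-dT primers before biotin labelling. The mice were on the C57BL/6 background. The design names biological replicates, and no source used here gives the sex, litter or array date of the animals.

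The deposited values are on a log2 scale. The submitters' processing notes name RMA, with no version, which corrects background, makes the arrays' distributions alike and summarises the probes of each probe set. In the deposited table the median of each of the 45101 probe sets over the 4 arrays was 0, the largest departure being 5e-07, so each probe set's own median had been subtracted. Differences between arrays are kept by this step and the expression level of a gene is lost. The log base is not stated in the labels. It was inferred from the values: they fall on the steps that single-precision numbers between 2 and 16 have, which is the range of RMA log2 values. The same steps place 25.6% of the probe sets at a lowest original value of 8 or more, 56.6% at 4 to 8 and 17.6% at 2 to 4, and 124 could not be placed. This class is coarse, since 16.1% of the brightest class also fitted the next coarser step. The number of arrays limits the precision, and no measure of signal over background was used.

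The 64 control probe sets were kept out of the tests. Of the other 45037, 34945 name 1 gene symbol, 932 name several and 9160 name none. A gene's value was the mean over its probe sets that name it alone, which gave 18193 genes from the 34945 probe sets. Of these, 34741 had a gene record in the RefSeq table of GRCm38.p6 and took its symbol. The others kept the symbol of the array annotation. Where a gene's probe sets differ, this mean lies between them, so a probe set that shows no difference pulls the gene's fold towards 1. Probe sets with no single gene entered only the test of each probe set by itself. Pthlh had no value in this set and is not analysed here.

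The groups were compared in limma 3.58.1 under R 4.3.3, with a linear model per gene on the group alone and a moderated two-sided test (eBayes). Differences are Ift88-deleted minus control. Adjusted p values are Benjamini-Hochberg over all 18193 genes, with a threshold of 0.05 and no fold limit. The design fixed before the data were examined had asked for a spread that follows the level and for the brightest probe set of each gene. Neither can be had once levels are subtracted, so the fit without a trend and the mean over probe sets, both listed beforehand as other settings to try, were used, and this was decided before any test was run. With 2 arrays against 2 there are 3 splits, and an exact two-sided permutation test cannot give a p under 0.333, so only the model that pools the spread over genes was used. The 2 residual degrees of freedom were joined by 3.83 prior degrees of freedom.

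Before the data were examined, 32 gene lists were fixed for cilia, signalling pathways, cartilage zones, cell cycle, metabolism, stress, sex and other cell types. The 31 with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, which compares a list with all other genes. Camera with an estimated correlation and fry were run beside it. For each list the members past the threshold were also counted adjusted over the list alone. These counts are not corrected for the number of lists, some of which share genes, so some such calls can arise by chance.

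Genes were named by a rule fixed before the data were examined: Ift88; 12 genes per direction, first those past the threshold and then those with an unadjusted p under 0.05 and groups that do not overlap, by size of difference, without predicted genes; 4 members of each list past its threshold in the list's direction and at most 2 of each other list; and 13 fixed genes of the Hedgehog, Wnt, cartilage and cell cycle groups. Members past the threshold over their list alone are named as well.

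Alternatives were renewed quantile normalization, subtraction of each array's median, each probe set by itself, a test against a log2 difference of 0.5, no moderation, a threshold of 0.1, the replicate number as a block, other list tests, lists without shared genes and leaving out each array. Chosen after seeing the data were probe sets of the brightest class only, the dimmest class left out, a robust spread without trend, and genes on X and Y left out. The analysis was tested on simulated data in 20 draws with as many genes and 50 changed genes per size of change. In these 45.3% of 2-fold and 95.9% of 4-fold changes were called, with 9.55 false calls per draw. When none was changed, 0.1 genes were called per draw. The simulated noise was normal, independent between genes, and had the spread of the fitted model. Genes that shift together between arrays were not simulated, so the false calls do not measure the error on the real arrays. With 200 changed genes in a draw the adjusted threshold is easier to reach than here, where a gene of median spread needs a log2 difference of 2.59 to pass at the top rank. Figures were drawn with matplotlib 3.10.9.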

Results

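The series holds 4 arrays, 2 of control and 2 of Ift88-deleted growth plate chondrocytes at postnatal day 7. Ift88 encodes a protein of the intraflagellar transport machinery that builds the primary cilium, and the comparison asks which genes differ when the cilium is lost from cartilage. Values are log2 relative to the median of the 4 arrays for each probe set, so they give differences and no levels. The SD over genes of the difference between the group means was 0.246, that between both control arrays 0.339 and that between both Ift88-deleted arrays 0.239. The first principal component, with 52.1% of the variance, set control 1 (score -30.8) apart from control 2 (3.4), Ift88-deleted 1 (8.5) and Ift88-deleted 2 (19).

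Xist and Eif2s3y were the 2 genes of 18193 that passed the threshold in Ift88-deleted against control samples. Xist, the RNA that coats the inactive X chromosome of female cells (X, 103460373 to 103483233, GRCm38.p6), fell 164.5-fold (log2 difference -7.36, SE 0.141, n = 2 per group, adjusted p = 9.275e-05). Eif2s3y, a translation initiation factor gene on Y (1010562 to 1049134), rose 10.1-fold (log2 difference 3.34, SE 0.158, adjusted p = 0.00876). That value is the mean of a probe set that was 96.3-fold higher and one that was 1.06-fold higher. Of the other Y-linked genes of the list, Uty had a difference of 1.63 (adjusted p = 0.0673) and Kdm5d of 1.69 (adjusted p = 0.102). Tested by probe set, 1 of Kdm5d (27.3-fold, adjusted p = 0.00782) and 2 of Uty (12.8-fold, adjusted p = 0.0199, and 4.66-fold, adjusted p = 0.0416) rose. Both control arrays had the high Xist and low Y-linked values, and both Ift88-deleted arrays the opposite, so sex by these genes and genotype divide the arrays in the same way, and this holds beside every gene group given here. The 4 members of the sex-linked list passed adjusted over the list alone.

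With the genes on X and Y left out, an alternative chosen after seeing the data, limma called 0 genes, and 1052 had an unadjusted p under 0.05. Over all genes 1085 had such a p, 416 higher and 669 lower, where chance gives 910. The groups did not overlap in 33.3% of the genes, which is the share chance gives. At least 2-fold differences with groups apart were found for 30 genes higher and 70 lower. At an adjusted p under 0.1 there were 11 genes, 4 higher and 7 lower. The count was 56 without Ift88-deleted replicate 1 and 38 without Ift88-deleted replicate 2. It was 2 without control replicate 1 (Prg4 and Xist) and 2 without control replicate 2 (Dner and Xist), so that Eif2s3y passed in neither.

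Among genes with an unadjusted p under 0.05 and groups that do not overlap, those with the largest differences outside the sex chromosomes did not pass over all genes and are given as values. Higher in both Ift88-deleted arrays were Tpbg, a Wnt-inhibiting membrane glycoprotein (2.39, SE 0.232, adjusted p = 0.0982), Efemp1, an extracellular matrix fibulin (2.35, SE 0.412), Chad, the cartilage matrix protein chondroadherin (2.13, SE 0.253), Mamdc2 (1.81), Thbs2, a thrombospondin (1.51, SE 0.609), Lef1 (1.43), Ninl (1.40), Calml3 (1.38) and Pla2g7 (1.37). Lower in both were Dner, a Notch ligand (-2.89, SE 0.573), Gli1 (-2.62), Ddn (-2.42), Lsp1 (-2.40, SE 0.171, adjusted p = 0.0615), Itgb8, an integrin subunit (-2.13), Tnni2, fast skeletal troponin I (-1.96, SE 0.156, adjusted p = 0.0673), Syt8 (-1.88), Gdf10 (-1.86), Vit (-1.84), Dmrta1 (-1.81, SE 0.597) and H2-DMb2, a class II antigen presentation gene (-1.81, SE 0.152, adjusted p = 0.0673). Tested by itself, 1 probe set of Tnni2 (9.01-fold lower) and 1 of H2-DMb2 (6.10-fold lower) passed, each with an adjusted p of 0.0416, while another of each gene was 1.08-fold and 1.05-fold lower. Single arrays carried part of these values: Thbs2 was at 0.54 and Calml3 at 0.86 without Ift88-deleted replicate 1, Thbs2 at 2.48 and Pla2g7 at 0.75 without Ift88-deleted replicate 2, and Dmrta1 at -0.82 without control replicate 1 and -2.81 without control replicate 2.

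**Figure D1:**
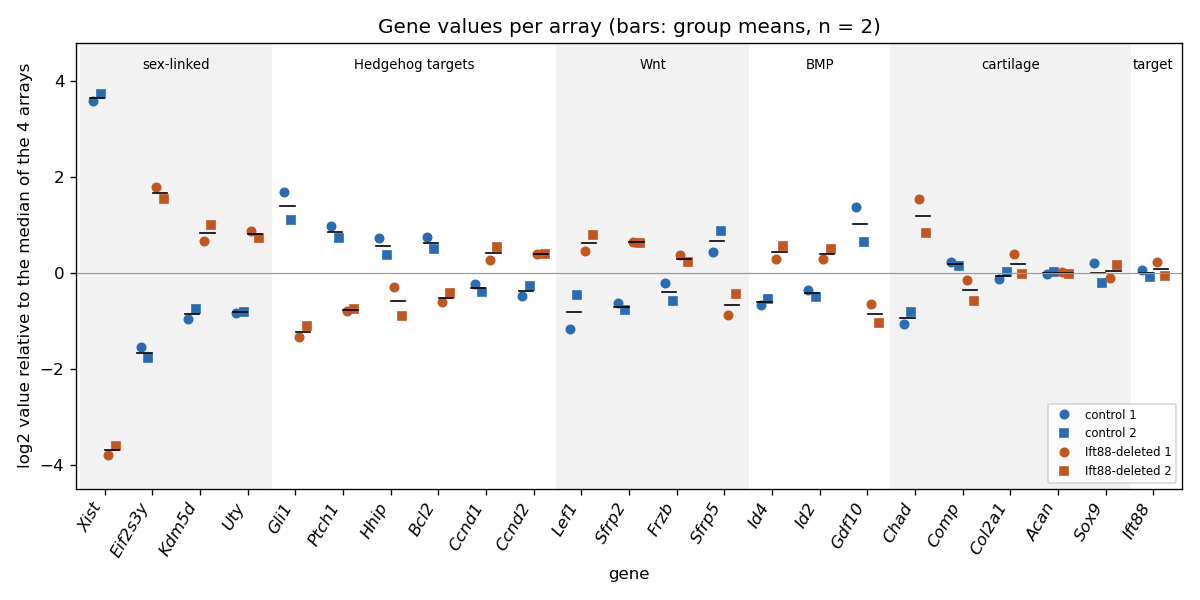
Values per array of genes named in the text, as log2 relative to the median of the 4 arrays (y axis), by gene (x axis), with black bars for the mean of 2 arrays. The sex-linked genes part the groups, with a difference of -7.36 for Xist, as do Gli1 (-2.62) and Ptch1 (-1.62), while Ift88 (0.08) does not.

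No difference in Ift88 itself was detected. Its single probe set gave a log2 difference of 0.08 (SE 0.154, 95% interval -0.30 to 0.46, adjusted p = 1). The gene lies on chromosome 14 (57424064 to 57517936), and where the probe set sits relative to the deleted exons was not analysed here, so this value does not test the deletion. The sign turned without Ift88-deleted replicate 1 (-0.06).

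Of the 31 gene lists 5 passed at the preset correlation, 1 higher and 4 lower, and 0 passed with an estimated correlation or with fry. Each of the 5 also passed under at least 1 of the other splits of the arrays into 2 and 2. The count was 11 without control replicate 1, 9 without control replicate 2, 10 without Ift88-deleted replicate 1 and 15 without Ift88-deleted replicate 2, and 17 of the 26 lists that did not pass with all arrays did in at least 1 of these fits. Neither cilia list passed with all arrays. The 31 intraflagellar transport and motor genes had a median difference of -0.152, 21 of them below 0 (adjusted p = 0.0746), with Ift20 at -0.57 and Ttc30a1 at -0.51 (-0.19 without control replicate 1 and -0.83 without control replicate 2). Its median was 0.225 in control 1 and 0.002, -0.049 and -0.039 in control 2 and the Ift88-deleted arrays, and it passed downward without control replicate 2 (adjusted p = 0.000565) and without Ift88-deleted replicate 2 (adjusted p = 0.0358). The 34 genes of the BBSome, transition zone and ciliary membrane had a median of -0.018 (adjusted p = 0.892), with Arl3 at -0.49 and B9d1 at -0.46 (-0.10 without control replicate 1 and -0.83 without control replicate 2), and passed upward without control replicate 1 (adjusted p = 0.0341). No member of either list passed adjusted over the list alone.

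Several direct readouts of Hedgehog signalling, which the primary cilium transduces, had lower values in both Ift88-deleted arrays. Gli1, a transcription factor induced by the pathway (10, 127329882 to 127341579), was 6.16-fold lower (log2 difference -2.62, SE 0.218), and Ptch1, the Hedgehog receptor and feedback inhibitor (13, 63508328 to 63573460), 3.08-fold lower (-1.62, SE 0.14). Over all genes their adjusted p values were 0.0673 and 0.0683. Of the 16 measured Hedgehog target genes 0 passed over all genes and 6 passed adjusted over the list alone: Gli1, Ptch1, the ligand-binding inhibitor Hhip (-1.15, SE 0.238) and the survival gene Bcl2 (-1.14, SE 0.153) fell by this test, and the cyclins Ccnd1 (0.72, SE 0.151) and Ccnd2 (0.77, SE 0.136) rose. The list as a whole did not pass (median -0.013, mean -0.332, adjusted p = 0.123). Of its members 7 lay above 0 and 9 below. The list was fixed with no direction expected of each member, so these counts do not show whether signalling rose or fell. The list test looks for a shift in 1 direction, so a list whose members move both ways can fail it. Leaving out 1 array gave medians of -0.24 (control replicate 1), 0.07 (control replicate 2), 0.06 (Ift88-deleted replicate 1) and -0.09 (Ift88-deleted replicate 2). The Ptch1 value averages probe sets that were 4.43-fold lower, 7.01-fold lower and 1.06-fold higher, and tested by itself the first passed (adjusted p = 0.0416), while that of Gli1 did not (adjusted p = 0.0911). Over all genes, Gli1 and Ptch1 passed after renewed quantile normalization and with probe sets of the brightest class only. Neither setting is separate support. The renewed normalization evens the spread of the arrays, which was widest in control 1 (SD 0.289, against 0.173 to 0.223 in the others). Gli1 has 1 probe set, of the brightest class, so that setting left its value unchanged. Over the list alone 0 members were called without moderation of the spread. Hedgehog pathway components had a median of 0.065 (adjusted p = 0.197), with Gsk3b at 0.39 and Gli3 at 0.29 (0.17 without Ift88-deleted replicate 2). Ihh, the growth plate's Hedgehog ligand, was at 0.17 (SE 0.325), with -0.35 without Ift88-deleted replicate 1 and 0.68 without Ift88-deleted replicate 2.

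Wnt/beta-catenin target genes were higher as a list in the Ift88-deleted arrays: 18 of 23 members lay above 0, with a median of 0.136 (adjusted p = 0.00278 at the preset correlation, adjusted p = 0.940 with an estimated correlation). Lef1, a transcription factor of the pathway (1.43, SE 0.263, the mean of probe sets 6.30-fold and 1.16-fold higher), and Ccnd1 (0.72) rose adjusted over the list alone, and 0 passed over all genes. Lgr6 (0.90), Znrf3 (0.45) and Axin2 (0.28, SE 0.173) did not pass. Lgr6 was at 0.19 without Ift88-deleted replicate 1 and 1.61 without Ift88-deleted replicate 2. Axin2, whose probe sets were at 0.65 and -0.10, was at 0.10 without control replicate 1, 0.45 without control replicate 2 and 0.16 without Ift88-deleted replicate 1. Without control replicate 1 the list's call was lost (median 0.06, adjusted p = 0.162). Secreted Wnt antagonists moved both ways. Adjusted over the list alone Sfrp2 (1.35, SE 0.129) and Frzb (0.71, SE 0.169) rose and Sfrp5 (-1.33, SE 0.218, the mean of probe sets 5.85-fold and 1.08-fold lower) fell, and the list did not pass (median 0.067, adjusted p = 0.0939). Wnt ligands, receptors and polarity genes had a median of -0.04 (adjusted p = 0.349), with Wnt5a at -0.64 and Scrib at -0.48, which were at -0.41 and -0.30 without control replicate 1, and Wnt5a at -0.42 without Ift88-deleted replicate 2.

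BMP and TGF-beta genes held members of both directions. Adjusted over the list alone Id4 (1.04, SE 0.149) and Id2 (0.82, SE 0.142), which BMP signals induce, rose, and the ligand Gdf10 (-1.86, SE 0.27) fell, while the 36 genes had a median of 0.077 (adjusted p = 0.215). FGF and MAP kinase feedback genes had a median of 0.022 (adjusted p = 0.127), with Spry2 at 0.69 (0.21 without control replicate 1 and 1.17 without control replicate 2) and Fgfr1 at 0.50. The IGF and growth hormone list had a median of -0.032 (adjusted p = 0.715), with Igf1r at -0.66 and Stc2 at -0.47 (-0.28 without Ift88-deleted replicate 2).

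Cartilage matrix genes did not pass as a list, and 1 of them passed adjusted over the list alone. The 29 cartilage matrix and identity genes had a median of 0.018, a mean of 0.03 and a downward test (adjusted p = 0.892), with Col2a1, the main cartilage collagen, at 0.25 (SE 0.176), Acan at 0.00 (SE 0.122), Sox9 at 0.04 (SE 0.19) and Comp at -0.54. Chad (2.13) was the member that passed. Col2a1 was at 0.04 without Ift88-deleted replicate 1 and 0.45 without Ift88-deleted replicate 2, Comp at -0.32 without Ift88-deleted replicate 2, and Acan, Sox9 and Col10a1 took both signs as single arrays were left out. In the list of resting zone and articular chondrocyte genes Sfrp5 and Fxyd2 (-1.44) fell and Ucma (1.09) rose over the list alone (19 genes, median -0.226, adjusted p = 0.0939). Its largest difference, that of Prg4 (-3.87), did not pass and was at -0.11 without control replicate 2. Control 2 was also the higher control for Sfrp5 (0.88 against 0.45) and Fxyd2 (1.06 against 0.43). Without control replicate 2 Sfrp5 was at -1.11 and Fxyd2 at -1.12. Among 24 prehypertrophic and hypertrophic genes Pla2g5 (1.09) rose over the list alone, Col10a1, the marker collagen of hypertrophic cells, was at 0.13 (SE 0.379), and the list had a median of 0.038, a mean of -0.008 and an upward test (adjusted p = 0.715). Matrix proteases and their inhibitors had a median of -0.012, a mean of -0.101 and an upward test (adjusted p = 0.892).

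Genes of energy metabolism were lower as lists in the Ift88-deleted arrays. Of 34 hypoxia and glycolysis genes 32 lay below 0 (median -0.35, adjusted p = 9.94e-13), and of 41 oxidative phosphorylation genes 39 did (median -0.258, adjusted p = 3.455e-11). Both calls were lost with an estimated correlation (adjusted p = 0.940 for each), and without control replicate 1 the medians were -0.20 and -0.16. Adjusted over the list alone Bnip3 (-0.84), Aldoa, an enzyme of glycolysis (fold 1.67 lower), Car12 and Ndrg1 fell, and Car9 (-0.999), Egln3 (-0.80) and Ero1a (-0.74) did not pass. Egln3 was at -0.41 and Ero1a at -0.30 without control replicate 1, Ero1a at -1.19 without control replicate 2 and Car9 at -0.49 without Ift88-deleted replicate 1. Of the respiratory chain Ndufa1 (-0.80), Ndufb3 (-0.74), Cox5a (-0.72) and Ndufb10 (-0.65) had the largest differences, and 0 passed. Ndufb3 and Ndufb10 were at -0.33 and -0.27 without control replicate 1 and at -1.16 and -1.03 without control replicate 2. The median of the oxidative phosphorylation genes was 0.308 in control 1, 0.048 in control 2, -0.058 in Ift88-deleted 1 and -0.195 in Ift88-deleted 2. Some control probe sets moved with the groups as well, where chance puts groups apart in 33.3%. The difference between 3′ and 5′ probe sets was lower with groups apart for 18S (-0.23) and Actb (-0.15). By group mean, with overlap, it was lower for Gapdh (-0.18), Tfrc (-0.06) and Pcx (-0.04). The Gapdh control probe sets themselves were lower with groups apart (3′ -0.746, 5′ -0.569, middle -0.384). The bioD and cre spike-ins were higher with groups apart, by 0.156 to 0.348. Other control probe sets, such as DapX-5 (-0.202) and PheX-3 (-0.141), were lower with groups apart.

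Dividing-cell genes were lower as a list, with control 1 alone standing high. The 33 G2/M genes passed (median -0.261, adjusted p = 0.00258, and adjusted p = 0.945 with an estimated correlation), with Ube2c at -0.77, Mki67 at -0.57, Cdca8 at -0.56 and Cenpe at -0.50. Their median was 0.397 in control 1 and -0.073 in control 2, against -0.034 and -0.048 in the Ift88-deleted arrays, and without control replicate 1 the difference turned to 0.04. In that fit Ube2c was at -0.49, Mki67 at -0.34, Cdca8 at -0.15 and Cenpe at -0.13, and without control replicate 2 Cdca8 was at -0.98 and Cenpe at -0.87. With probe sets of the brightest class the call was lost (adjusted p = 0.0667). S-phase genes had a median of -0.074 (adjusted p = 0.123), which was 0.06 without control replicate 1 and -0.25 without control replicate 2. Of them Rfc4 was at -0.73 (-0.21 without control replicate 1 and -1.26 without control replicate 2). Cdc6 was at -0.54 (-0.34 without control replicate 1 and -0.30 without Ift88-deleted replicate 2). Negative regulators and p53 targets had a median of -0.004 (adjusted p = 0.831), with Cdkn1a at -0.61 (-0.32 without Ift88-deleted replicate 2) and Cdkn2d at -0.46 (-0.22 without control replicate 1 and -0.70 without control replicate 2).

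Markers of other tissues differed between the groups in part of the muscle list and stood high in single arrays for others. The skeletal muscle list passed downward (27 genes, median -0.083, adjusted p = 0.0253, and adjusted p = 0.945 with an estimated correlation), where Tnni2 (-1.96), Tnnc2 (-1.08) and Mylpf (-1.05) fell over the list alone and Myh1 (-0.62, with -0.13 without control replicate 2 and -1.10 without control replicate 1) did not pass. Its call was lost without control replicate 2 (median 0.02, adjusted p = 0.85), with the replicate number as a block (adjusted p = 0.0561) and with probe sets of the brightest class (adjusted p = 0.0536). Prg4, the lubricin of the joint surface, stood at 7.52 in control 2 and at 0.01, -0.19 and -0.01 in control 1 and both Ift88-deleted arrays. Control 2 also had high values of the protease Mmp9 (2.46), Mmp13 (2.45), Acp5 of osteoclasts (1.84), the erythroid genes Hemgn (2.23) and Car2 (2.12), S100a8 (1.60), S100a9 (1.34) and Egr1 (2.86). Ift88-deleted 1 had high Postn (3.47) and Aspn (3.004), fibroblast and perichondrium genes. It also lay above Ift88-deleted 2 for Thbs2 (2.04 against 0.11) and Efemp1 (2.05 against 0.76). The lists of osteoclast (median -0.107, adjusted p = 0.297), erythroid (-0.126, adjusted p = 0.173), neutrophil (-0.062, adjusted p = 0.612), macrophage and leukocyte (0.099, adjusted p = 0.123) and perichondrium markers (0.061, adjusted p = 0.123) did not pass. Each of these medians took both signs with 1 array left out. Without control replicate 1 and without control replicate 2 they were -0.28 and 0.07 (osteoclast), -0.27 and 0.03 (erythroid), -0.25 and 0.17 (neutrophil) and -0.05 and 0.25 (macrophage and leukocyte). The perichondrium median was -0.14 without Ift88-deleted replicate 1 and 0.21 without Ift88-deleted replicate 2.

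**Figure D2:**
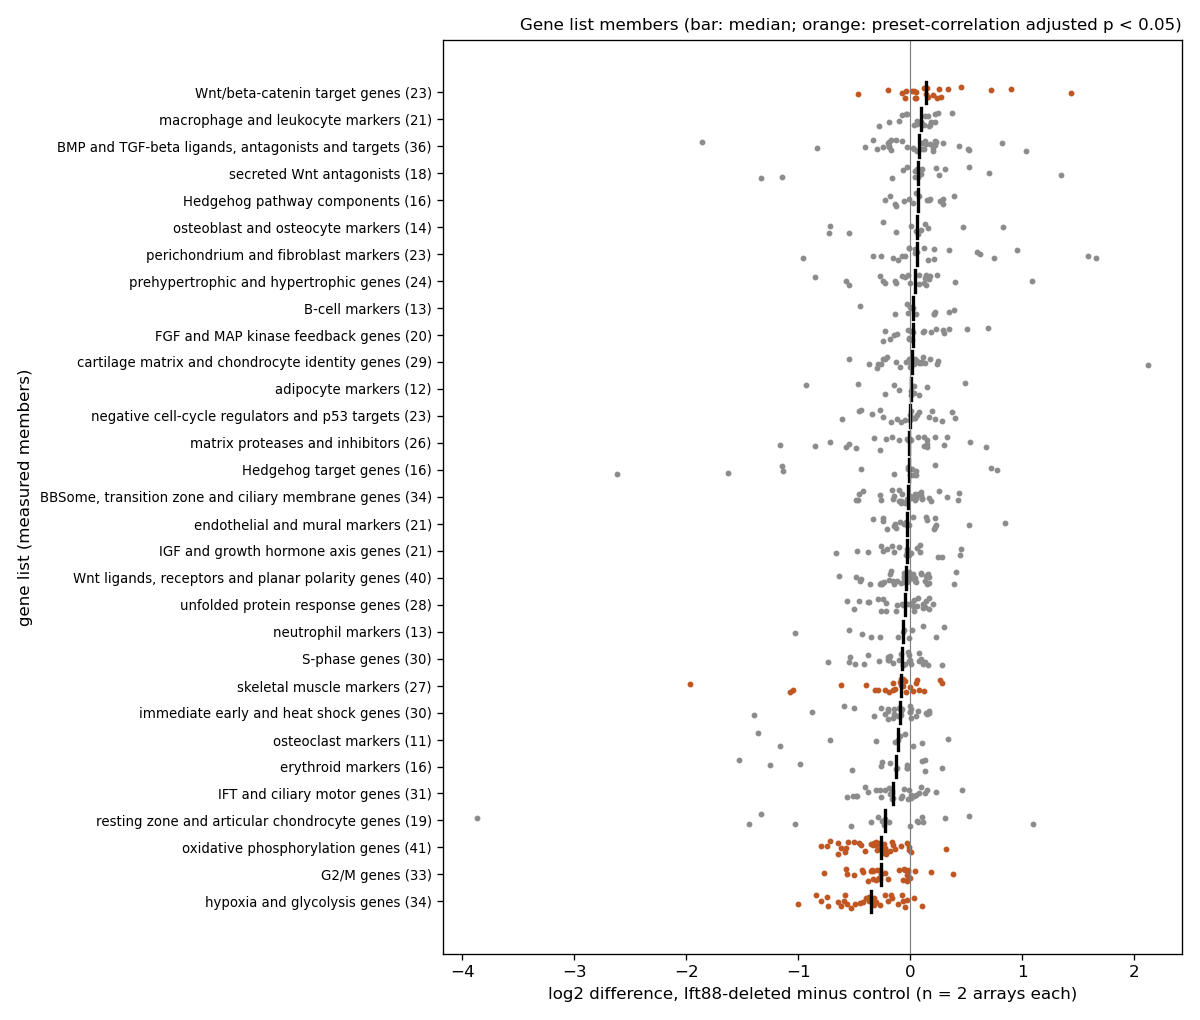
Log2 difference between Ift88-deleted and control means (x axis, 2 arrays each) of the members of 31 gene lists (y axis, members in brackets). Points are genes, bars are medians and orange lists have an adjusted p under 0.05 at the preset correlation; the medians run from -0.35 for hypoxia and glycolysis genes to 0.136 for Wnt/beta-catenin targets.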

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

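The signals given here were looked for after the results were seen. Among the probe sets that belong to no single gene, and so to no gene value of the report, 9 passed the threshold and are among the 20 found when each probe set was tested by itself, 6 higher and 3 lower in the Ift88-deleted arrays. The 6 higher ones stood above both control arrays, with log2 differences of 7.77, 4.79, 4.36, 3.85, 2.42 and 2.22 and adjusted p values from 0.00227 to 0.0322. The 3 lower ones had log2 differences of -3.78, -2.40 and -2.36. The 9 probe sets part the arrays as Xist and the Y-linked genes do, so sex and genotype cannot be told apart for them either. Ddx3y of the sex-linked list had no gene value, and whether any of these probe sets measures it was not checked. The genes behind them are not analysed here.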

How the results depend on the processing

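The brightest-class, dimmest-class, robust-spread and X and Y alternatives were chosen after seeing the data, and all others were planned. The planned filters on dim genes by percentile and the robust spread with a trend were not run, since levels are lost. The count of 2 changed genes stayed at 2 with each array's median subtracted, a test against 0.5, the dimmest class left out and a robust spread. It was 14 after renewed quantile normalization, 1 (Xist) with the replicate number as a block, which no label says pairs the arrays, 1 (Oas1c) without moderation, 20 for each probe set by itself, 11 at a threshold of 0.1, 11 with the brightest class, and 0 with X and Y genes left out, since both called genes lie there. Leaving out an array gave 2 to 56 genes, the lone array then being assumed to vary like the other group. The count of 5 lists stayed within 4 to 5 under the other settings (4 with the replicate block, where skeletal muscle was lost; the robust spread does not enter this test) but was 0 with an estimated correlation, 0 with fry, 9 with shared genes left out, 3 with the brightest class and 9 to 15 with an array left out. The 6 Hedgehog targets called over the list alone became 0 without moderation, 4 with the brightest class and 5 to 10 with an array left out. The Ift88 difference ran from -0.064 to 0.22 with an array left out, below 0 without Ift88-deleted replicate 1. Of 96 named genes 0 changed sign under renewed quantile normalization, subtraction of each array's median or the brightest class. The replicate block, the robust spread and the dimmest class left out cannot alter a gene's difference, so they do not test its sign. A probe set of the other sign was found for 8 named genes, and 12 named genes changed sign with an array left out. Their ranges, and that of the G2/M median (-0.47 to 0.042), were Acan -0.011 to 0.018, Col10a1 -0.46 to 0.72, Egr1 -2.86 to 1.09, Ptprc -0.66 to 0.11, Mmp9 -2.57 to 0.24, S100a8 -2.07 to 0.0063, S100a9 -1.49 to 0.39, Mmp13 -2.45 to 0.75, Sox9 -0.17 to 0.25, Postn -0.41 to 3.72, Acp5 -2.79 to 0.063, Ihh -0.35 to 0.68. Apart from the X and Y genes and the looser threshold, the cause was not tested. How signal over background limits these values was not tested either.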

Other observations

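Bone and stress genes gave single differences that passed adjusted over their lists alone, and 0 passed over all genes. Over all genes the adjusted p was 0.458 for Cthrc1, 0.287 for Ier3 and 0.449 for Lpl. Of 14 osteoblast and osteocyte markers Dmp1, a matrix protein of osteocytes, fell (log2 difference -0.72, SE 0.122) and Cthrc1, a secreted collagen-related protein, rose (0.83, SE 0.174), while Omd was at -0.73 (-0.29 without Ift88-deleted replicate 2 and -1.17 without Ift88-deleted replicate 1), and the list had a median of 0.061, a mean of -0.034 and a downward test (adjusted p = 0.892). The median of the osteoblast and osteocyte list was -0.26 without Ift88-deleted replicate 1 and 0.31 without Ift88-deleted replicate 2. Of 30 immediate early and heat shock genes Ier3 fell (-1.39, SE 0.215), and the list had a median of -0.094 (adjusted p = 0.123). Lpl, a lipoprotein lipase, fell (-0.93, SE 0.194) among 12 adipocyte markers (median 0.006, mean -0.089, adjusted p = 0.522). Unfolded protein response genes had a median of -0.047 (adjusted p = 0.327), with Manf at -0.57 (-0.26 without control replicate 1, -0.88 without control replicate 2 and -0.29 without Ift88-deleted replicate 2) and Edem1 at -0.50 (-0.30 without control replicate 1, -0.94 without Ift88-deleted replicate 1 and -0.07 without Ift88-deleted replicate 2). B-cell markers had a median of 0.026 (adjusted p = 0.297), with Vpreb1 at -0.45 (-0.27 without control replicate 1) and Ebf1 at 0.39 (0.60 without control replicate 1, 0.17 without control replicate 2 and 0.25 without Ift88-deleted replicate 2). Endothelial and mural markers had a median of -0.032, a mean of 0.043 and an upward test (adjusted p = 0.831), with Vwf at 0.84 and Rgs5 at 0.52 (from 0.07 without Ift88-deleted replicate 1 to 0.98 without Ift88-deleted replicate 2).

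Of the tests given next, those of sex, of control 2, of the count of all genes over other splits, of the muscle markers and of the differences within groups were chosen only after the result was seen.

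Gli1, Ptch1, Hhip and Bcl2 were lower in the Ift88-deleted arrays. Other tissue in control 2 as a part of these differences stays open, since without that array a single control is left. The median difference of the 4 genes was -1.39 with control 2 and -1.54 without it. Control 1, where Prg4 was at 0.01, lay above control 2 for Gli1 (1.69 against 1.11), Ptch1 (0.97 against 0.74) and Hhip (0.74 against 0.37). Bcl2 was at -1.01 without control replicate 1 and at -1.14 with all arrays. These values, which rest on control 1, argue against tissue in control 2 as the whole source for the 4 genes. The 4 genes were noticed because both controls lay above both Ift88-deleted arrays, which fixes the sign without control 2 but not the size. The whole list was at a median of 0.07 without control 2. Sex cannot be told apart from genotype here, because Xist (-7.36) parts the 4 arrays exactly as the genotype does and no array has the level of the other group. The real split gave 6 Hedgehog targets over the list alone and the highest of the other splits 1, so 1 of the 3 splits gave as many, and over all genes 1 of 3 splits gave as many as the real 2, the highest other giving 0; 3 splits are too few for a share under 0.05. Loss of cilia therefore stays open as an untested hypothesis beside sex and other tissue, the latter in control 2 only as a part of the differences.

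Tnni2, Lsp1 and Syt8, which were lower in both Ift88-deleted arrays, are neighbours on chromosome 7 (Syt8 from 142434850, Tnni2 from 142441816, Lsp1 from 142458223). Skeletal muscle in the control tissue as the whole source is argued against: the other 26 muscle markers had a median difference of -0.081 (quartiles -0.216 and 0.017) against -1.96 for Tnni2, with the abundant Acta1 at -0.29 and Ckm at -0.08, although Tnnc2 (-1.08) and Mylpf (-1.05) fell over the list alone with Tnni2. A locus that differs between the groups may account for them. Of 90 autosomal genes with a 2-fold difference and groups apart 5 had such a neighbour within 3 measured genes. That is above the 95th percentile of 1000 random gene sets, which was 4. But 3 of the 5 are Tnni2, Lsp1 and Syt8 themselves. The other 2, H2-DMa (-1.76) and H2-DMb2 on chromosome 17, are as many as the median of the random sets. Against the other splits of the arrays the 5 of 90 were higher in number than their 2 of 19 and 4 of 27. They were lower in share (5.56% against 10.5% and 14.8%). The wording of the test did not say which was meant, so the question stays open. Genotype and sex stay open too.

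The hypoxia, glycolysis and oxidative phosphorylation lists were lower in the Ift88-deleted arrays, with a median of -0.305 over their 75 members. A shift shared by the whole brightest class is argued against, since 6554 of its genes outside the lists had a median difference of -0.013. The class is coarse and holds every gene placed at 8 or more. A shift of only the very brightest genes within it therefore stays open. A gradient that also runs within groups stays open: the members differed by a median of 0.253 between both control arrays and 0.116 between both Ift88-deleted arrays, neither as large as the difference between groups nor far below it. The other splits of the arrays gave 13 and 16 lists past the threshold against the real 5, and the 13 included both of these metabolic lists, which points to a structure of the samples that the preset correlation does not allow for. Genotype and sex cannot be set apart here either, and the 3′ to 5′ differences of 18S and Actb and the spike-in differences, which part the groups, were not weighed as a cause.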
